A study of Mus musculus with 31 samples.

How the data were processed

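Per the labels' protocols, cells came from C57BL/6 mice or from lines, RNA was extracted with RNeasy Micro or Mini kits as total RNA, and libraries followed a standard Illumina protocol. Per the submitters' processing notes, reads were mapped to the mm9 genome, and Subread, featureCounts and limma were named. Versions of these programs were not given in the sources used here. The count values used for every test were deposited by the authors as 1 table of read counts per gene and library, and the processing notes name featureCounts without saying its settings or role. The log2 FPKM values were deposited by the authors as 1 file per sample, and the steps behind them were not given beyond the name limma. These values followed counts divided by gene length with a further shift per library that grew with expression. No source described this shift, and its cause was not tested.

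The table of counts held 26286 genes, of which 540 had no symbol and were left out of library sizes and tests. These carried 0.785% of all counts, between 0.244% and 1.685% per library. Symbols were those of the deposited table. Gene classes and current symbols came from a RefSeq table, to which 24176 gene identifiers matched. No coordinates were taken from it, since its genome build differs from mm9. Per-sample FPKM files held 14261 genes, 14258 in 2 of the libraries, and no immunoglobulin gene was among them. Each of the 31 FPKM files matched the counts of its own library best, with a lowest correlation across genes of 0.9978 among genes of at least 50 counts. The design written from the labels assumed counts in the per-sample files. The table of the series took their place, with all of its columns mapped to samples. Immunoglobulin genes numbered 257, of which 12 were constant regions. Totals per library, from 13.2 M to 141.4 M counts, left between 12.61 M and 138.05 M counts outside immunoglobulin genes, which sets the precision for all other genes.

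Genes were filtered with filterByExpr by group and scaled with TMM factors in edgeR 4.0.16 under R 4.3.3. A single model with 1 mean per group was fitted to the 31 libraries by the edgeR quasi-likelihood method, leaving 10 residual degrees of freedom. The common dispersion was 0.0303, a biological variation of 17.4%. Contrasts between group means were tested with the quasi-likelihood F test and adjusted with the Benjamini-Hochberg procedure, with a threshold of 0.05. The 11 comparisons, an interaction and a shared signature (log2 change of at least 1) were drawn from this fit. Immunoglobulin shares of ex vivo libraries were compared with an exact permutation test. CPM values used TMM-adjusted library sizes, and log2 CPM values used a prior count of 2.

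The 25 gene lists named 497 entries, of which 494 matched a gene. They were tested with camera at a preset correlation of 0.01 and, as alternatives, with an estimated correlation and with fry. Camera asks whether list members rank apart from other genes. With fry no such comparison is made, since it tests whether the members change at all. Some lists hold genes of the sort gates, which were kept in their counts and tests. These are Cr2 (marginal zone), Fcer2a (follicular), Itgam (B1), Fas (germinal center), and Prdm1 and Sdc1 (plasma cell identity). B cell identity holds Cd19, Cr2 and Fcer2a. Where a gate used such a gene, it could set the direction of that member in advance. Where a gene had no counts in an arm, the fold was computed against a floor of 3 counts over the group. Where it had between 1 and 3 counts, the ratio is given with a 95% counting interval. Shares in single libraries carry 95% Wilson intervals. Groups with 1 library were described by CPM, and list medians were placed among 10000 random lists of the same size matched on expression.

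Genes were named by a rule of the design. It took the 8 largest rises and falls per comparison among called genes of at least 10 CPM whose libraries did not overlap, the 4 strongest called members of each list, the genes of the sort gates and the transcription factor list. The text gives examples from that set, picked with values in view, and the account of how results depend on processing covers the whole set. Genes that share reads with near-identical copies are uncertain in all comparisons.

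DESeq2 1.42.0 (Wald test) and limma 3.58.1 (voom) were run on the same group means. Other alternatives were DESeq2 size factors, library totals, different filters, removal of immunoglobulin genes, a replicate block, fits of the compared groups or arms alone, and fits without each library in turn. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

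The pipeline was tried on simulated counts with a dispersion of 0.03 and 200 changed genes, 100 at 2-fold and 100 at 4-fold. In the ex vivo comparison of secreting and B cells, edgeR recovered 98% and 100% of them, with 4.3% of its calls false. In LPS plasmablasts against blasts it recovered 25% and 96%, with 4.7% false. There limma-voom recovered 17% and 96% with 5% false, and DESeq2 27% and 96% with 12.1% false, above the nominal rate. Between the LPS plasmablast populations edgeR recovered 56% and 95%, and between bone marrow and splenic plasma cells 40% and 95%, with 6.2% false. The signature rule recovered 190 of 200 genes changed 4-fold. A seeded list of 30 genes had camera p = 4.77e-56, or 9e-09 with an estimated correlation and 1.89e-10 by fry. An unchanged list had camera p = 0.171, or 0.151 with an estimated correlation and 0.0237 by fry. In the simulation, all other genes had equal means in the groups compared, and rises and falls were balanced. Dispersion was the same for all genes and groups. The false shares therefore do not cover a shift in immunoglobulin share or the wider spread of the FoB and B1 pairs.

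Replicate pairs correlated between 0.9175 (B1) and 0.997 (CD40L/IL4/IL5 plasmablasts) in log2 CPM across genes, with 0.9463 for FoB. Their differences exceeded counting noise, with chi-square per degree of freedom between 4.08 and 555.47 over genes of at least 40 counts, so none of the pairs was a copy. Over 1000 variable genes, the first principal components held 48.3%, 15.7%, 13.2% and 5.1% of the variance. Dixon's test was not run, since no group had more than 3 libraries. The pairs of FoB and B1 lay further apart than the others, with a standard deviation of log2 differences of 0.758 and 0.958 against 0.18 to 0.479. All libraries were kept.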

Results

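The series measured RNA by sequencing in mouse B cells and antibody-secreting cells, as 31 libraries in 21 groups. Ex vivo groups were follicular B cells (FoB, n = 2), marginal zone B cells (MZB, n = 2), peritoneal B1 cells (B1, n = 2), germinal center B cells (GCB, n = 2), splenic plasmablasts (SplPB, n = 1), splenic plasma cells (SplPC, n = 3) and bone marrow plasma cells (BMPC, n = 1). Cultured groups were LPS blasts (n = 1), LPS plasmablasts without surface Syndecan1 (n = 2), LPS plasmablasts with it (n = 2), CD40L/IL4 blasts (n = 2) and CD40L/IL4/IL5 plasmablasts (n = 2). Resting B cells, 5 stages of a CD40L division series, CD40L/IL4 plasmablasts and the lines A20 and MPC11 had 1 library each. In that series, division 0 had 24 hours of CD40L and IL4. Divisions 1, 3, 5 and 7 had 96 hours of CD40L, IL4 and IL5. Deposited counts summed to between 13.2 M and 141.4 M per library, with both germinal center libraries deepest. After filtering, 16782 genes were tested, of which 248 were immunoglobulin genes. The comparisons, gene lists and the tests behind each main count were fixed before the data were examined. Runs without the first FoB and B1 libraries, with thinned libraries, without markers of other cells, and with limma on the deposited FPKM values were added later.

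Nothing in the sources says that replicates came from separate animals or cultures, so p-values measure the spread between these samples alone. That spread was pooled over the 9 groups with 2 or 3 libraries, not taken from the groups compared alone. The FoB and B1 pairs lay further apart than the others, so the pooled spread can be too small for their comparisons. Where an arm held a single library (SplPB, BMPC, LPS blasts, CD40L/IL4 plasmablasts), that library was assumed to vary like the replicated groups. Fold changes are log2 values with a standard error (SE), taken as the absolute change divided by the square root of the F statistic. With few counts in an arm this SE can be smaller than counting error. Adjusted p-values of genes come from the edgeR quasi-likelihood F test with the Benjamini-Hochberg correction over all genes tested. Adjusted p-values of gene lists come from camera at a preset correlation, corrected over the 25 lists of a comparison. With an estimated correlation instead, camera still called plasma cell identity, the unfolded protein response, ER translocation, N-glycosylation and the follicular list in ex vivo secreting cells, in each LPS plasmablast population against blasts and in CD40L/IL4/IL5 plasmablasts. It also kept the marginal zone and follicular lists in MZB, the B1, dendritic and follicular lists in B1, the follicular list in GCB, and the neutrophil, marginal zone and follicular lists in BMPC.

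How much of the RNA of secreting cells coded for antibody was asked first. Immunoglobulin genes took 69.1 ± 6.01% of counts (mean ± SD, n = 5) in ex vivo secreting cells and 1.70 ± 0.350% (n = 8) in ex vivo B cells, a difference of 67.4 points (exact two-sided permutation p = 0.00155, the smallest this test can give for these arms). Constant-region genes alone took 46.7 ± 3.57% against 1.27 ± 0.294%. The joining chain gene Igj, which links IgM and IgA into polymers, stood at 103600 ± 6010 CPM in SplPC (n = 3) and 26.1 ± 12.0 CPM in FoB (n = 2). CPM values use TMM-adjusted library sizes, with factors of 0.405 to 0.458 in SplPC and 1.393 to 1.43 in FoB. They are therefore not shares of counts like the percentages here. Among cultured cells, immunoglobulin genes took 60.8 ± 2.58% in LPS plasmablasts with Syndecan1 (n = 2), 48.4 ± 2.79% in those without (n = 2) and 42.2 ± 0.206% in CD40L/IL4/IL5 plasmablasts (n = 2). Single libraries held 73.98% in BMPC (95% Wilson interval 73.97 to 73.99), 58.88% in SplPB (58.87 to 58.9) and 28.14% in CD40L/IL4 plasmablasts (28.12 to 28.16). The plasmacytoma line MPC11 held 7.788% (7.774 to 7.802) and the B lymphoma line A20 0.5529% (0.5494 to 0.5564). These intervals, and the floors used for genes without counts below, cover counting error only.

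**Figure D1:**
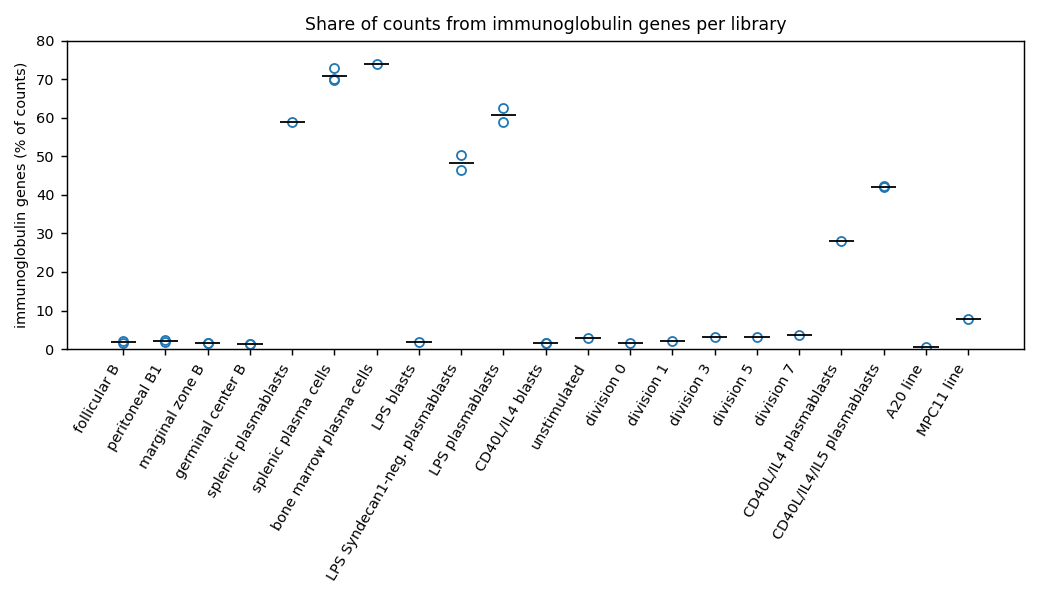
Share of counts from immunoglobulin genes in each library. Circles mark libraries and lines mark group means.

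Genes that set ex vivo antibody-secreting cells (SplPB, SplPC and BMPC, n = 5) apart from ex vivo B cells (FoB, MZB, B1 and GCB, n = 8) were sought with each population weighted equally. Tnfrsf17, the BCMA receptor for survival signals from APRIL and BAFF, rose by 11.95 ± 0.15 (adjusted p = 2.89e-16). Prg2, known as an eosinophil granule protein, rose by 12.2 ± 0.29 (adjusted p = 6.88e-14) and averaged 1003 CPM in secreting cells. The metallothionein Mt2 rose by 11.24 ± 0.16. Xbp1, which drives the secretory program, rose by 5.6 ± 0.07 (adjusted p = 3.88e-16), from 82.9 ± 7.02 CPM in FoB (n = 2) to 3918 ± 299 CPM in SplPC (n = 3). Prdm1, the gene of the Blimp1 repressor whose reporter served as a gate, rose by 6.56 ± 0.17, and Irf4, required for plasma cells, rose by 3.31 ± 0.12. The costimulatory receptor gene Cd28 rose by 7.66 ± 0.26. Pax5, which holds B cell identity, fell by 7 ± 0.25 (adjusted p = 4.01e-12). Cxcr5, which guides B cells into follicles, fell by 7.1 ± 0.44, and the class II transactivator Ciita fell by 5.77 ± 0.25. The repressors Bcl6 and Bach2, which delay plasma cell formation, fell by 5.38 ± 0.14 and 3.87 ± 0.14.

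In all, 11445 genes differed between ex vivo secreting cells and B cells, 5477 higher and 5968 lower (edgeR quasi-likelihood, adjusted p under 0.05). A 2-arm fit called 7379, 3478 higher and 3901 lower. Without the first FoB and B1 libraries, which departed from their partners, the count was 12149. Of the unfolded protein response list 39 of 39 members were higher (median 3.11, adjusted p = 2.51e-21), led by the ER degradation gene Derl3, which rose by 6.56 ± 0.08. All 43 tested members of ER translocation and vesicle transport were higher (median 2.28, adjusted p = 2.51e-21), among them the coat gene Sec24d, which rose by 5.42 ± 0.06. Of plasma cell identity 14 of 15 were higher (median 4.34, adjusted p = 8.06e-10). Of N-glycosylation 26 of 28 were higher (median 1.43, adjusted p = 1.93e-11), but its median turned to -0.22 when libraries were scaled by totals. Amino acid supply, with Pycr1 of proline synthesis up by 7.84 ± 0.1, had 18 of 20 members higher (median 1.5, adjusted p = 1.97e-07), with a median of -0.15 under library totals (adjusted p = 0.3 with an estimated correlation). Of B cell identity 27 of 28 were lower (median -3.47, adjusted p = 2.21e-10; adjusted p = 0.096 with an estimated correlation). MHC class II presentation had 11 of 12 members lower (median -2.89, adjusted p = 0.000278; adjusted p = 0.321 with an estimated correlation). The follicular list was lower in 9 of 9 members (median -3.37, adjusted p = 0.000278).

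In ex vivo secreting cells against B cells, cell cycle genes were higher in 9 and lower in 13 of 38 (median -0.17, adjusted p = 0.411), and transcription factors of the stages higher in 12 and lower in 20 of 32 (median -0.89, adjusted p = 0.26). Survival and death genes were higher in 10 and lower in 4 of 15 (median 0.48, adjusted p = 0.118), with a median of -1.17 under library totals. Bcl2l1, an inhibitor of cell death, was among the higher ones, rising by 2.13 ± 0.09. Migration and adhesion had 10 members higher, Ccr10 of mucosal homing rising by 9.77 ± 0.26, and 8 lower, Ccr7 of lymph node homing falling by 4.85 ± 0.24. The migration median was 0.2 and the mean -0.24 (adjusted p = 0.987), and library totals turned the median to -1.44. For interferon-stimulated genes, with 7 higher and 8 lower of 19, the median was 0, the mean -0.28 and the direction given by fry upward. The marginal zone list was lower in 11 of 15 (median -2.31, adjusted p = 0.017; adjusted p = 0.148 with an estimated correlation). Germinal center genes were lower in 9 of 17 (10 when adjusted over the list alone), B1 genes higher in 6 and lower in 6 of 15, and activation genes lower in 10 and higher in 5 of 19. Of the immediate early list 10 of 15 were higher (median 1.16, adjusted p = 0.0535), the median being -0.48 under library totals.

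Scaling by library totals in place of TMM made most calls of this kind lower, where antibody transcripts filled the secreting libraries. In ex vivo secreting cells against B cells it gave 1752 genes higher and 12248 lower, and moved the median of all genes from -0.094 to -1.688 log2. With DESeq2 size factors the higher side was the larger one, at 5764 against 5597 genes here, 3849 against 3706 in LPS plasmablasts and 3403 against 3200 in Syndecan1-negative ones, each against blasts. Directions given here are therefore relative to the bulk of genes, not amounts per cell. The labels record no sequencing batch, so batch could not be separated from cell type. Sex-linked genes followed the arms in part, since Y-linked genes summed to at most 0.153 CPM in the ex vivo B cell libraries and to between 37.7 and 88.1 CPM in 4 of the 5 secreting ones.

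**Figure D2:**
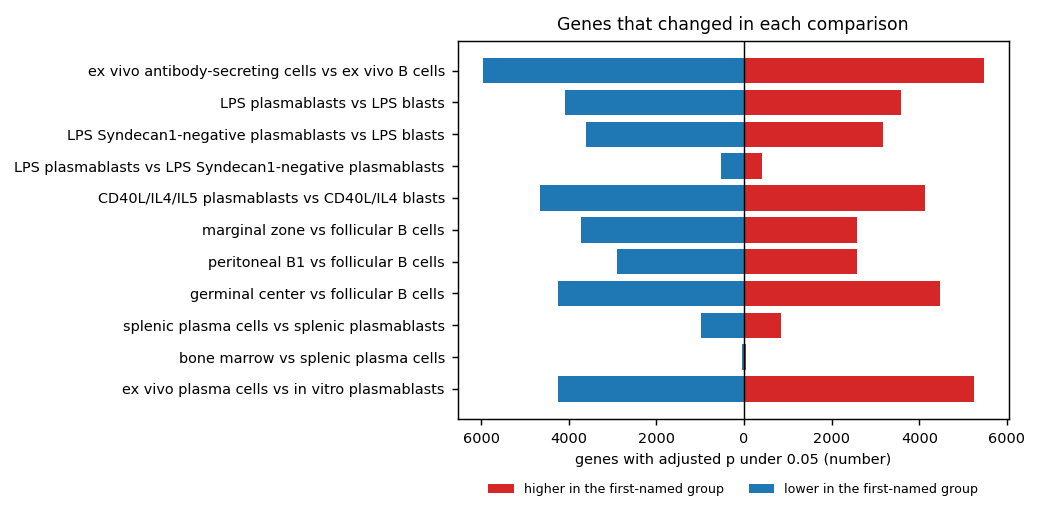
Genes called higher (red) and lower (blue) in the first-named group of each of 11 comparisons by edgeR at an adjusted p under 0.05.

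LPS plasmablasts with Syndecan1 (n = 2) were compared with LPS blasts (n = 1) of the same culture hour to ask what changes when a dividing cell begins secretion. The plasmablasts were sorted with and the blasts without the Blimp1 reporter. As a check of that gate, Prdm1 rose by 4.97 ± 0.42 (edgeR adjusted p = 2.51e-07). Xbp1 rose by 5.53 ± 0.19 (edgeR adjusted p = 2.06e-10) and Irf4 by 4.41 ± 0.32. Epcam, an adhesion gene, rose by 9.17 ± 0.41 (adjusted p = 9.18e-10), and the inhibitory receptor gene Ctla4 by 7.77 ± 0.65. Eomes, a T-box factor best known from T and NK cells, had a ratio of 905 (counting interval 162 to 35800). C4bp, a complement regulator without counts in the blast library, was at least 216-fold higher, taking 3 counts over the group as the floor. Klf2, a quiescence and homing factor, fell by 7.13 ± 0.38 (adjusted p = 3.33e-09), the endosomal DNA sensor Tlr9 by 6.16 ± 0.18 and Pax5 by 4.28 ± 0.3. Aicda, the switching and mutation enzyme, fell by 5.78 ± 0.58.

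In LPS plasmablasts 7676 genes differed from blasts, 3580 higher and 4096 lower (edgeR, adjusted p under 0.05). The count was 9282 without the first FoB and B1 libraries, which enter the pooled spread. The unfolded protein response was higher in 39 of 39 members (median 3.12, adjusted p = 8.19e-27), Txndc5 of disulfide folding rising by 5.79 ± 0.32. ER translocation was higher in 41 of 43 (median 1.97, adjusted p = 4.19e-25), N-glycosylation in 26 of 28 (27 over the list alone, adjusted p = 4.21e-14) and plasma cell identity in 13 of 15 (median 3.84, adjusted p = 1.83e-08). B cell identity was lower in 23 of 28 (24 over the list alone, median -2.33, adjusted p = 1.83e-08; adjusted p = 0.16 with an estimated correlation), and the follicular list in 8 of 9 (median -4.9, adjusted p = 3.96e-05). MHC class II presentation was lower in 10 of 12 (adjusted p = 0.00026; adjusted p = 0.416 with an estimated correlation). Amino acid supply was higher in 14 of 20 (15 over the list alone, adjusted p = 2.45e-07), its median -0.08 under library totals (adjusted p = 0.36 with an estimated correlation). Interferon-stimulated genes were lower in 11 of 19 (13 over the list alone, median -1.18, adjusted p = 0.0657), with Ifit3, an antiviral effector, falling by 5.67 ± 0.42. Library totals gave 1190 genes higher and 10588 lower, with a median of -1.38 over all genes.

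Syndecan1-negative LPS plasmablasts (n = 2) were set against the same blasts (n = 1) to ask how far they had gone. As a check of the Blimp1 reporter gate, Prdm1 rose by 5.49 ± 0.43 (edgeR adjusted p = 1.78e-07). Xbp1 rose by 5.18 ± 0.19 (edgeR adjusted p = 4.25e-10). Bhlha15, the Mist1 factor of secretory cells, rose by 8.54 ± 0.51 (adjusted p = 1.43e-08), and Hid1, of dense-core granule sorting, by 8.24 ± 0.4. Klf2 fell by 6.84 ± 0.36 and the urokinase receptor Plaur by 6.83 ± 0.42. Fos rose by 8.59 ± 2.49 (adjusted p = 1.30e-02), and immediate early and stress genes were higher in 6 of 15 and lower in 2 (median 1.17, adjusted p = 0.282), or in 3 and 4 with library totals. The median level of that list was 3.68 log2 CPM in the blast library and 5.71 and 5.9 in the others, so handling was not separated from differentiation. The unfolded protein response was higher in 39 of 39 members (median 2.81, adjusted p = 1.77e-29), ER translocation in 41 of 43 (adjusted p = 4.55e-27) and plasma cell identity in 12 of 15 (median 3.43, adjusted p = 7.32e-08). B cell identity was lower in 18 of 28 (adjusted p = 6.73e-07; adjusted p = 0.258 with an estimated correlation). In total 6767 genes differed, 3165 higher and 3602 lower. Library totals gave 1321 and 9398, with a median of -0.955 over all genes.

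What marks the step to surface Syndecan1 was asked by comparing LPS plasmablasts with it (n = 2) and without it (n = 2). As a check of the gate, Sdc1 rose by 2.92 ± 0.22 (edgeR adjusted p = 2.77e-05), from 7.82 ± 0.646 to 59.0 ± 10.9 CPM. Tnfrsf17 rose by 3.02 ± 0.22 (adjusted p = 2.77e-05), and Ly6c2, a surface antigen of plasma cells, by 2.21 ± 0.31 (adjusted p = 0.00103). Rgs13 and Rgs16, regulators of G-protein signals, fell by 4.2 ± 0.52 and 3.54 ± 0.5. Lymphotoxin beta, Ltb, fell by 3.07 ± 0.36 (adjusted p = 3.68e-04), the helper receptor Cd40 by 1.94 ± 0.28 and the costimulatory Cd86 by 1.81 ± 0.29. A fit of these groups alone called 2397 genes, 1202 higher and 1195 lower. With replicate number as a block, that fit gave 2628 higher and 2537 lower, though no label says that replicates were paired. The main fit called 934 genes, 401 higher and 533 lower. The count depended on single libraries: 610 without the first Syndecan1-negative library, 201 without the second, and 311 and 373 without the first and second Syndecan1-positive library. B cell identity was lower in 10 of 28 (18 over the list alone, median -0.61, adjusted p = 9.87e-10; adjusted p = 0.118 with an estimated correlation), and activation genes in 6 of 19 (12 over the list alone, adjusted p = 9.42e-07; adjusted p = 0.09 with an estimated correlation). The unfolded protein response was higher in 7 of 39 (10 over the list alone, median 0.25, adjusted p = 2.04e-07; adjusted p = 0.09 with an estimated correlation), and its median turned to -0.17 under library totals. Those totals gave 109 genes higher and 5159 lower, with a median of -0.379 over all genes. Without the second Syndecan1-negative library the split was 63 higher and 138 lower.

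CD40L/IL4/IL5 plasmablasts (n = 2) were compared with CD40L/IL4 blasts (n = 2) to ask the same of a culture driven by T cell signals. As a check of the Syndecan1 gate of these plasmablasts, Sdc1 rose by 6.28 ± 0.26. Hid1 rose by 9.2 ± 0.31 (edgeR adjusted p = 3.04e-11), Prdm1 by 6.34 ± 0.33 and Xbp1 by 3.37 ± 0.13. The adhesion gene Cdh2 was at least 549-fold and the iron binder Ltf at least 541-fold higher. Tnfrsf17 had a ratio of 1160 (counting interval 398 to 5650). Fcer2a, the CD23 receptor for IgE, fell by 6.96 ± 0.56 (adjusted p = 1.07e-07), the amino acid oxidase gene Il4i1 by 6.38 ± 0.48, the costimulatory ligand gene Icosl by 6.29 ± 0.55 and Bcl6 by 5.73 ± 0.19. In total 8771 genes differed, 4122 higher and 4649 lower, and 10117 without the first FoB and B1 libraries. The unfolded protein response was higher in 39 of 39 (median 2.83, adjusted p = 1.23e-24), with the ER isomerase Fkbp11 rising by 6.8 ± 0.22. ER translocation was higher in 41 of 43 (median 2.01, adjusted p = 3.68e-24), plasma cell identity in 14 of 15 (median 3.79, adjusted p = 2.76e-09) and amino acid supply in 19 of 20 (median 1.84, adjusted p = 8.09e-10; adjusted p = 0.187 with an estimated correlation). B cell identity was lower in 27 of 28 (median -3.74, adjusted p = 2.78e-12; adjusted p = 0.0606 with an estimated correlation), MHC class II presentation in 12 of 12 (median -2.23, adjusted p = 2.49e-05; adjusted p = 0.259 with an estimated correlation). Library totals gave 1789 genes higher and 9536 lower, with a median of -0.915 over all genes. The arms differed in IL5 and in hours of culture as well as in stage.

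Whether the step from blast to plasmablast differed between the LPS and the CD40L cultures was tested as an interaction (n = 2 and 1 against n = 2 and 2). Lag3, an inhibitory receptor gene, rose by 7.56 ± 0.5 with LPS and fell by 0.98 ± 0.33 with CD40L (edgeR adjusted p of the difference = 2.90e-07). Pdcd1, the PD-1 gene, rose by 4.65 ± 0.43 with LPS and fell by 1.8 ± 0.29 with CD40L (adjusted p = 1.25e-06). The cystine transporter gene Slc7a11 did the same, at 5.15 ± 0.54 and -1.24 ± 0.28 (adjusted p = 6.24e-06). In the other direction, the guanylate-binding Gbp7 fell by 3.96 ± 0.19 with LPS and rose by 1.63 ± 0.16 with CD40L (adjusted p = 2.05e-08), and the galectin Lgals3 fell by 5.3 ± 0.41 and rose by 0.88 ± 0.23. The difference was called for 3250 genes, 1564 with the higher effect in LPS and 1686 with the lower, and for 6721 in a fit of these groups alone, with 3015 higher and 3706 lower. Of the 3250 genes, 422 were called in both cultures with opposite signs. Library totals gave 790 and 4120, with a median of -0.422 over all genes.

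Genes shared by secreting cells of 3 origins were taken from the comparisons that share no library: ex vivo, LPS and CD40L/IL4/IL5. A gene had to be called by edgeR in the same direction in each, with a log2 change of at least 1. The shared set held 1384 higher genes, where 74.2 would be expected of independent lists of 3352, 2385 and 2615 genes, and 887 lower genes, where 51.1 would be expected of 2606, 2263 and 2438. The lists came from a single fit with a common filter, scaling and spread per gene, so they were not independent. The expected numbers are a reference and not a test. Of the higher genes 229 were immunoglobulin genes, so 1155 were others, and 1 of the lower genes was. Without the first FoB and B1 libraries the sets held 1449 and 910. Removing immunoglobulin genes before scaling gave 1206 and 835, and library totals gave 580 and 5529. The set took in 34 of 39 unfolded protein response, 36 of 43 ER translocation and 13 of 15 plasma cell identity genes as higher, and 18 of 28 B cell identity, 10 of 12 MHC class II and 8 of 9 follicular genes as lower. A single cell cycle gene belonged to it. In libraries that did not choose the set, the median of its higher genes was 3.88 log2 CPM in CD40L/IL4 plasmablasts, 4.07 in MPC11, 2.42 in A20, 2.22 at division 1 and 2.59 at division 7. Its lower genes stood at 3.16 in CD40L/IL4 plasmablasts, 0.86 in MPC11, 2.66 in A20, 3.92 at division 1 and 4.08 at division 7.

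**Figure D3:**
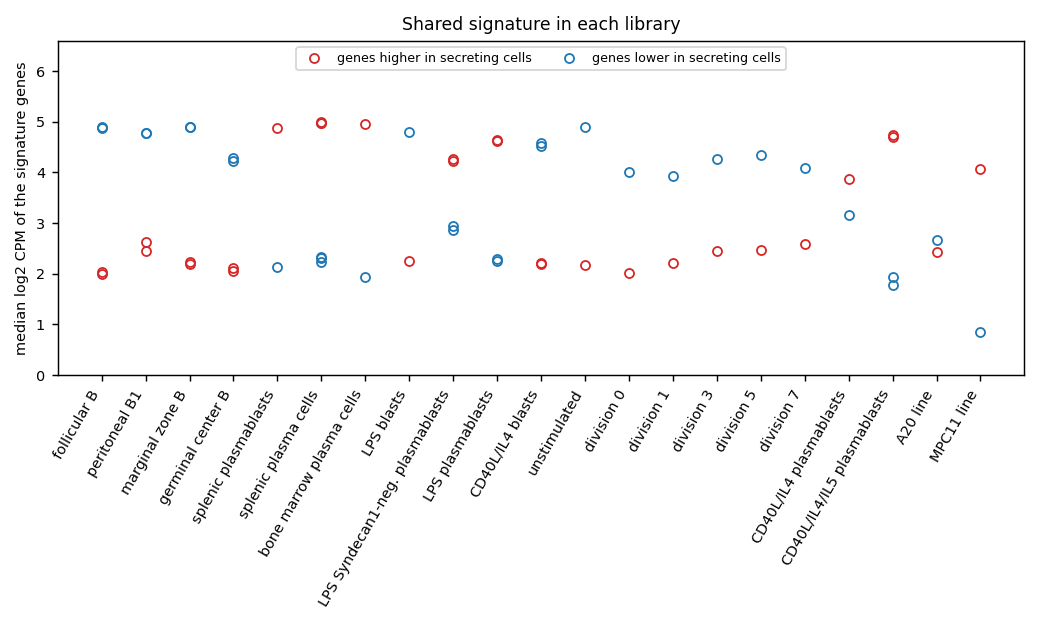
Median log2 CPM of the shared signature per library, red for its higher genes and blue for its lower genes.

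Marginal zone (n = 2) and follicular B cells (n = 2) were compared to ask which genes part the splenic B cell compartments. S1pr3, a receptor for sphingosine phosphate, rose by 3.93 ± 0.33 (edgeR adjusted p = 2.01e-06), from 14.1 ± 7.70 to 213.6 ± 29.1 CPM. The tetraspanin Cd9 rose by 3.42 ± 0.15 (adjusted p = 2.74e-08), the meiotic cohesin Rec8 by 4.94 ± 0.22 and the membrane repair gene Myof by 3.48 ± 0.35. Prdm1 rose by 2.2 ± 0.31. Among gate genes Cr2 rose by 1.84 ± 0.39 and Fcer2a fell by 3.02 ± 0.46. Sdc1 fell by 3.86 ± 0.26, Klf2 by 3.01 ± 0.27 and Bach2 by 2.6 ± 0.18. The marginal zone list, which holds the gate gene Cr2, was higher in 14 of 15 members (median 2.37, camera adjusted p = 1.15e-10). The follicular list, which holds the gate gene Fcer2a, was lower in 8 of 9 (median -1.92, camera adjusted p = 0.000248). Cell cycle genes were higher in 26 of 38 (28 over the list alone, median 1.22, adjusted p = 5.65e-07; adjusted p = 0.841 with an estimated correlation). Immediate early and stress genes were lower in 8 of 15 (9 over the list alone, median -1.49, adjusted p = 0.0692). The median level of that list was 5.15 log2 CPM in the first and 3.58 in the second FoB library, and 2.46 and 2.54 in the MZB libraries, so handling was not separated from cell type. ER translocation was lower in 26 of 43 (28 over the list alone, median -0.34, adjusted p = 3.32e-06; adjusted p = 0.603 with an estimated correlation). Of 6313 genes called, 2581 were higher and 3732 lower. The count was 4060 without the first MZB library and 7143, with 2678 higher and 4465 lower, without the first FoB and B1 libraries, and a fit of these groups alone gave 2845, with 1610 higher and 1235 lower. Which side held more genes depended on processing: library totals gave 3457 higher and 1884 lower, DESeq2 size factors 3210 and 2662, and removal of immunoglobulin genes 3056 and 2930.

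Peritoneal B1 cells (n = 2) were set against follicular B cells (n = 2), a comparison in which tissue differed too. Zbtb32, a repressor of class II genes, rose by 6.69 ± 0.25 (edgeR adjusted p = 1.11e-09), from 2.47 ± 0.693 to 258.7 ± 10.7 CPM. Sox5 and Bhlhe41, transcription factors of B1 cells, rose by 6.63 ± 0.34 and 4.8 ± 0.24, and Ctla4 by 6.93 ± 0.55. The gate gene Itgam rose by 5.65 ± 0.62, Cd5, a brake on antigen receptor signals, by 2.34 ± 0.32, and the gate gene Fcer2a fell by 5.19 ± 0.51. Vpreb3, a chaperone of immature B cells, fell by 5.41 ± 0.38 (adjusted p = 1.68e-07) and the chromatin organizer Satb1 by 4.08 ± 0.23. The B1 list was higher in 12 of 15 (13 over the list alone; median 3.51, or 3.66 with genes near 0 counts at their bound; adjusted p = 8.12e-11), the dendritic list in 7 of 12 (median 1.61, adjusted p = 0.00122), and the follicular list lower in 7 of 9 (median -1.44, adjusted p = 0.00127). B cell identity was lower in 18 of 28 (19 over the list alone, adjusted p = 8.46e-06; adjusted p = 0.341 with an estimated correlation), and interferon-stimulated genes in 11 of 19 (12 over the list alone, adjusted p = 0.00146; adjusted p = 0.586 with an estimated correlation). NK genes were also higher, in 6 of 10 (7 over the list alone, median 1.81, adjusted p = 0.00256; adjusted p = 0.392 with an estimated correlation), and erythroid genes lower in 8 of 12 (9 over the list alone; median -4.73, or -4.51 with bounds; adjusted p = 0.00106; adjusted p = 0.341 with an estimated correlation). Other cells in the sorts were thus not separated from B1 expression, for the dendritic list included. The 5474 calls comprised 2571 higher and 2903 lower genes. The count was 5387 without the first FoB and B1 libraries, but a fit of these groups alone gave 959, with 692 higher and 267 lower. Library totals turned the split to 2696 higher and 1836 lower, DESeq2 size factors to 2863 and 2015, and removal of immunoglobulin genes to 2698 and 2335.

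What separates germinal center (n = 2) from follicular B cells (n = 2) was asked next. Aicda rose by 8.45 ± 0.64 (edgeR adjusted p = 6.98e-08), from 1.17 ± 0.0218 to 411.7 ± 3.85 CPM. Gcsam, an adaptor that slows germinal center cell movement, rose by 9.9 ± 0.72, and S1pr2, which confines cells to the center, by 8.06 ± 0.34 (adjusted p = 2.64e-10). The proliferation marker Mki67 rose by 7.14 ± 0.56 and the gate gene Fas by 4.31 ± 0.23. Ccr7 fell by 6.69 ± 0.31 (adjusted p = 6.97e-10), the homing receptor Sell by 6.37 ± 0.33, the survival gene Bcl2 by 5.13 ± 0.22 and the interferon-stimulated Mx1 by 4.01 ± 0.52. Cell cycle genes were higher in 38 of 38 (median 4.98, adjusted p = 5.53e-22; adjusted p = 0.221 with an estimated correlation) and germinal center genes in 16 of 17 (median 4.63, adjusted p = 3.14e-10; adjusted p = 0.111 with an estimated correlation). Interferon-stimulated genes were lower in 18 of 19 (19 over the list alone, median -2.05, adjusted p = 3.9e-08; adjusted p = 0.221 with an estimated correlation), and the follicular list in 8 of 9 (9 over the list alone, median -2.47, adjusted p = 0.000104). Markers of other cells were lower too, T cell genes in 14 of 18 (15 over the list alone, median -2.81, adjusted p = 0.00318; adjusted p = 0.455 with an estimated correlation), erythroid genes in 9 of 12 (median -3.66, or -3.97 with bounds; adjusted p = 0.012; adjusted p = 0.455 with an estimated correlation) and neutrophil genes in 7 of 15 (median -2.91, adjusted p = 0.0211; adjusted p = 0.455 with an estimated correlation). NK genes were lower in 6 of 10 (7 over the list alone, median -1.42, adjusted p = 0.0211; adjusted p = 0.455 with an estimated correlation). RNA of other cells was thus not separated from the change in these B cells. The test called 8731 genes, 4473 higher and 4258 lower, but DESeq2 size factors gave 3984 and 4768 and library totals 3977 and 4511. With germinal center libraries thinned to the follicular depth the count was 8399, with 3970 higher and 4429 lower, and without the first FoB and B1 libraries 9480.

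Splenic plasma cells (n = 3) and splenic plasmablasts (n = 1) were compared to ask what changes late in differentiation. E2f8, a cell cycle repressor, fell by 3.48 ± 0.35 (edgeR adjusted p = 2.42e-05), the survivin gene Birc5 by 3.43 ± 0.3 (adjusted p = 8.76e-06) and Cep55, of abscission, by 3.26 ± 0.28. Mki67 stood at 872.3 CPM in the plasmablast library and 194.3 ± 27.4 CPM in plasma cells. Cxcr3, a receptor for inflammatory chemokines, fell by 2.71 ± 0.3. Mt2 rose by 2.2 ± 0.21 (adjusted p = 1.45e-05) and Tnfrsf17 by 1 ± 0.18. Bcl2 rose by 1.34 ± 0.23 while its relative Bcl2l1 fell by 1.14 ± 0.16. Cell cycle genes were lower in 37 of 38 (median -2.85, adjusted p = 1.23e-41; adjusted p = 0.217 with an estimated correlation). ER translocation was lower in 17 of 43 (19 over the list alone, median -0.3, adjusted p = 1.62e-10; adjusted p = 0.24 with an estimated correlation), Ssr2 of the translocon falling by 1.22 ± 0.13. The unfolded protein response was lower in 14 of 39 (16 lower and 3 higher over the list alone, adjusted p = 4.6e-05; adjusted p = 0.24 with an estimated correlation). In total 1825 genes differed, 850 higher and 975 lower, and 637 in a fit of these groups alone, with 224 higher and 413 lower. Library totals gave 237 and 5120, with a median of -0.401 over all genes.

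What parts plasma cells of different organs was asked with bone marrow (n = 1) against splenic plasma cells (n = 3). The calprotectin gene S100a8, abundant in neutrophils, rose by 6.44 ± 0.66 (edgeR adjusted p = 4.16e-03), from 0.244 ± 0.109 to 21.6 CPM. Mt2 rose by 1.82 ± 0.17 (adjusted p = 3.75e-04) and the syndecan Sdc4 by 0.96 ± 0.13. Sell fell by 1.89 ± 0.35 (adjusted p = 2.61e-02), the egress receptor S1pr1 by 1.64 ± 0.28, the RNA sensor Tlr7 by 1.37 ± 0.16 and Bcl6 by 1.99 ± 0.32. The test called 96 genes, 50 higher and 46 lower, and 165 without the first SplPC library. The neutrophil list was higher in 6 of 15 (12 over the list alone; median 5.73, or 5.64 with bounds; adjusted p = 1.44e-38). The marginal zone list was lower in 2 of 15 (6 over the list alone, median -0.51, adjusted p = 5.75e-07) and the follicular list in 1 of 9 (3 over the list alone, median -0.76, adjusted p = 0.000229). Interferon-stimulated genes were lower in 1 of 19 (6 over the list alone, median -0.83, adjusted p = 4.1e-06; adjusted p = 0.396 with an estimated correlation). Immediate early and stress genes were lower in 1 of 15 (6 over the list alone, median -1.71, adjusted p = 2.98e-06; adjusted p = 0.436 with an estimated correlation). Macrophage genes had a median of -2.1 (camera adjusted p = 4.1e-06, or 0.469 with an estimated correlation). The median level of neutrophil genes was 1.26 log2 CPM in bone marrow and -4.22 to -2.8 in the splenic libraries. For erythroid genes it was 3.44 against 0.36 to 2.13. Residual RNA of macrophages, neutrophils and erythroid cells, and handling, were thus not separated from organ. Processing changed the split: library totals gave 34 higher and 59 lower with a median of -0.156 over all genes, removal of immunoglobulin genes 22 and 38, the DESeq2 Wald test 87 and 123, limma-voom 89 and 12, limma on the deposited FPKM values 54 and 129, and a fit of these groups alone 4 higher genes.

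Plasma cells from tissue (SplPC and BMPC, n = 4) were compared with plasmablasts from culture. The culture arm held LPS, CD40L/IL4 and CD40L/IL4/IL5 plasmablasts (n = 5). Tnfrsf17 rose by 3.69 ± 0.12 in tissue cells (edgeR adjusted p = 6.68e-11), Cxcr3 by 5.75 ± 0.3 (adjusted p = 2.71e-09), Sdc1 by 2.73 ± 0.15 and Bcl2 by 2.6 ± 0.14. Slco4a1, an organic anion transporter, fell by 5.63 ± 0.14 (adjusted p = 9.29e-12), the IL-2 receptor Il2ra by 4.31 ± 0.17, the CD30 gene Tnfrsf8 by 7.23 ± 0.54, Bcl2l1 by 2.55 ± 0.13 and the spindle gene Tpx2 by 4.84 ± 0.33. Cell cycle genes were lower in 37 of 38 (median -3.79, adjusted p = 3.02e-18; adjusted p = 0.55 with an estimated correlation), and MHC class II presentation in 11 of 12 (median -1.88, adjusted p = 0.000392; adjusted p = 0.55 with an estimated correlation). Interferon-stimulated genes were higher in 13 of 19 (13 higher and 2 lower over the list alone, median 1.11, adjusted p = 0.0125; adjusted p = 0.582 with an estimated correlation). The 9496 genes called, 5260 higher and 4236 lower, reflect tissue, culture, stage, any difference in library handling and sex-linked expression together. Stage was not separated from culture, since plasma cells were set against plasmablasts. Cell cycle genes also fell from splenic plasmablasts to splenic plasma cells. Xist was under 1 CPM in 4 of the 5 cultured libraries and in none of the tissue ones. A 2-arm fit called 4446, 2240 higher and 2206 lower. Library totals gave 1963 and 9141, with a median of -0.672 over all genes.

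Markers of other cell types were measured in several populations. In tissue plasma cells against culture, macrophage genes were higher in 16 of 20 (18 over the list alone; median 7.65, or 6.89 with bounds; adjusted p = 0.00132; adjusted p = 0.582 with an estimated correlation), C1qa of complement being at least 994-fold higher. Erythroid genes were higher there in 10 of 12 (11 over the list alone; median 7.66, or 6.2 with bounds; adjusted p = 0.0159; adjusted p = 0.55 with an estimated correlation), with the globin gene Hba-a2 at least 2520-fold higher. In ex vivo secreting cells against ex vivo B cells, erythroid genes were higher in 8 of 12 (median 1.91, adjusted p = 0.135), neutrophil genes in 8 of 15 (median 3.98, adjusted p = 0.0713) and macrophage genes in 6 of 20 (median 0.64, adjusted p = 0.166), the last with a median of -0.99 under library totals. The same comparison had T cell genes lower in 10 of 18 (median -1.99, adjusted p = 0.0826), NK genes lower in 6 of 10 (adjusted p = 0.32) and dendritic genes higher in 4 and lower in 4 of 12 (adjusted p = 0.784). Platelet genes were higher in 2 and lower in 1 of 5, with a median of 1.16, a mean of -0.29 and a median of -0.48 under library totals (adjusted p = 0.53). In peritoneal B1 cells, macrophage genes were higher in 9 of 20 than in follicular cells (10 over the list alone, median 2.05, adjusted p = 0.19), and the lysozyme gene Lyz2 stood at 1492 CPM in the first and 101.7 CPM in the second library. Leaving all members of the other-cell lists out of the genes tested gave 11390 calls in ex vivo secreting cells against B cells and 90 in bone marrow against splenic plasma cells.

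**Figure D4:**
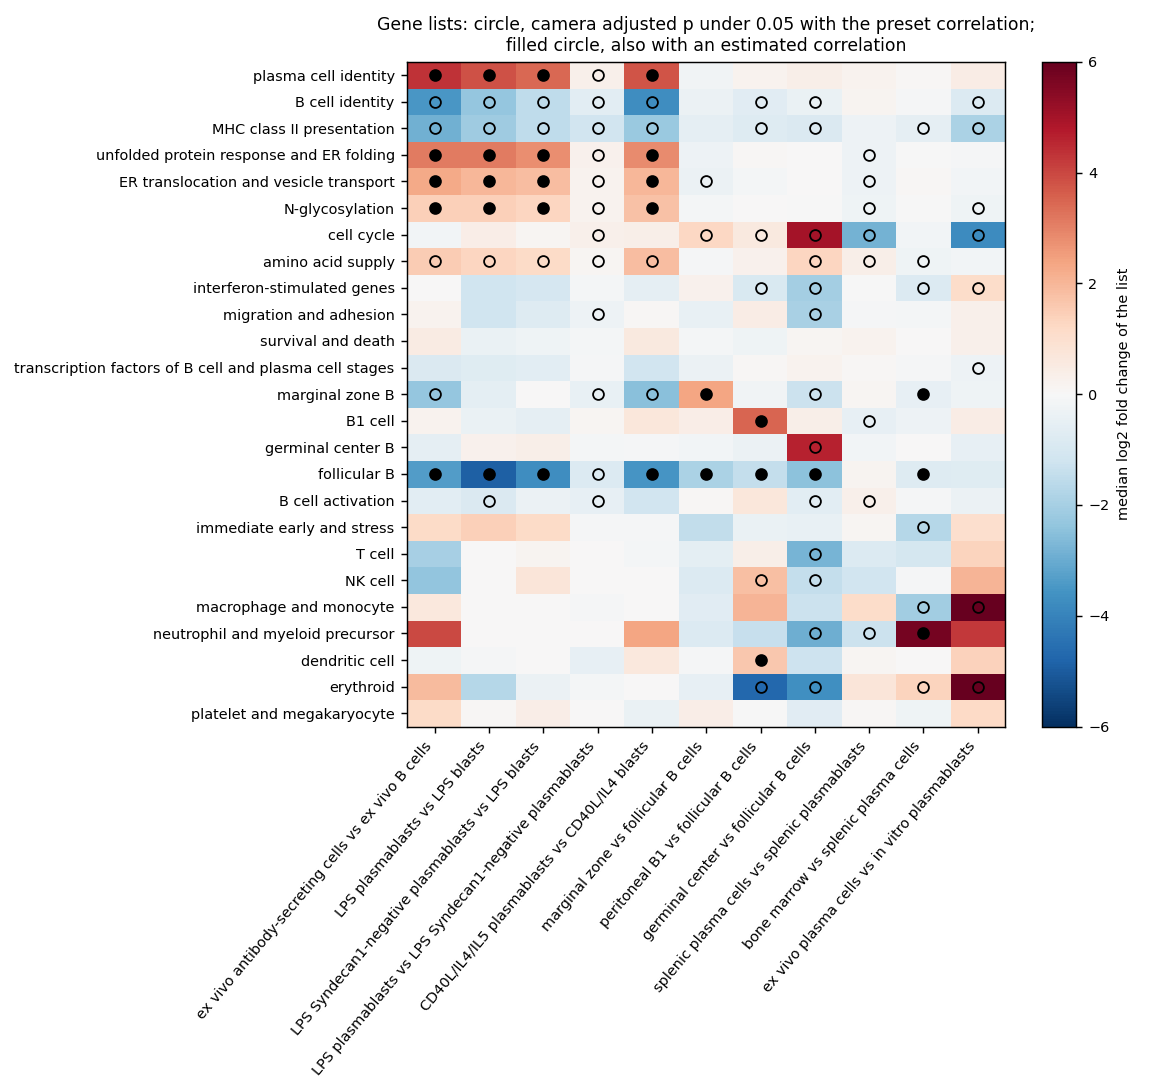
Median log2 fold change of each list (colour, clipped at 6) in each comparison. Circles mark camera at a preset correlation, filled ones also at an estimated correlation, and under library totals medians such as that of N-glycosylation in ex vivo secreting cells (-0.22) turn negative.

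How genes differed between division stages was described in CD40L cultures with 1 library per stage, and the design tested no contrast among them. The Y-linked genes summed to 0.168 CPM at division 1 and 36.3, 83.7 and 82.8 CPM at divisions 3, 5 and 7, so the animals or cultures behind the libraries could not be separated from division. Between the division 1 and division 7 libraries, 568 of 7841 genes were at least 2-fold higher and 610 at least 2-fold lower in the latter, the Y-linked Eif2s3y, Kdm5d and Ddx3y among the former. The germinal center gene Gcsam went from 0.673 to 44.9 CPM, and the mucin-like gene Parm1 from 4.94 to 160.5 CPM. The chemokine gene Ccl22 went from 2000 to 77.6 CPM, and Cr2 from 19.9 to 1.03 CPM. Among regulators, Prdm1 went from 2.97 to 10.6 CPM, Irf4 from 612.3 to 107.4 CPM and Xbp1 from 521.2 to 901.0 CPM. The median change of cell cycle genes was -1.05, at percentile 0 among 10000 random lists matched on expression, and that of activation genes -0.88, also at percentile 0. Plasma cell identity changed by 0.79 (percentile 99.98), with 5 of 15 members at least 2-fold higher and 3 at least 2-fold lower. The follicular list changed by 1.16 (percentile 100), B cell identity by 0.4 (percentile 99.92), MHC class II presentation by 0.65 (percentile 99.84) and immediate early and stress genes by -0.89 (percentile 0.01). These changes did not point to plasma cells alone. From division 7 to CD40L/IL4 plasmablasts, which were sorted on Syndecan1 and grown without IL5, Sdc1 went from 2.30 to 198.1 CPM and Prdm1 from 10.6 to 232.2 CPM. There the unfolded protein response had a median change of 1.66 (percentile 100) and 31 of 39 members rose at least 2-fold. Of the 1155 higher signature genes outside the immunoglobulin loci, 666 rose at least 2-fold on that step. Between resting cells and undivided cells after a day of stimulation, Ccl22 went from 2.29 to 3924 CPM and Fos from 682.6 to 0.662 CPM, along with Fosb, Dusp1 and Klf4. The median level of immediate early and stress genes was 8.74 log2 CPM in the resting and 4.69 in the undivided library, so handling of the cells was not separated from stimulation.

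**Figure D5:**
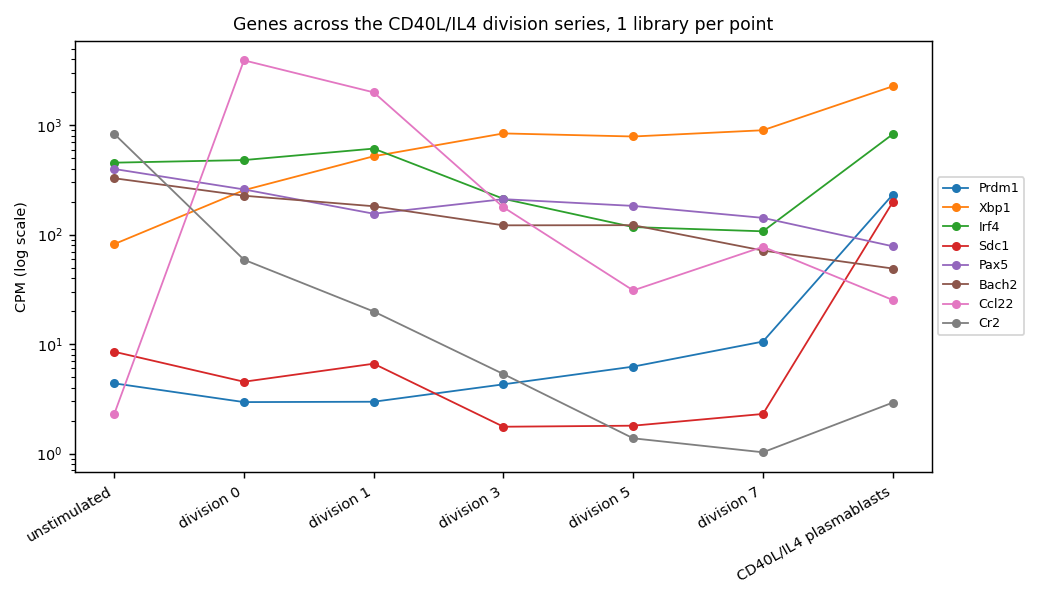
CPM of 8 genes along the CD40L division series on a log axis. Each point is 1 library.

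The lines A20 and MPC11, 1 library each, were described without a test. From A20 to MPC11 plasma cell identity changed by a median of 2.92 (percentile 100 among 10000 matched lists), with 13 of 15 members at least 2-fold higher. MHC class II presentation changed by -6.81 and B cell identity by -4.59, both at percentile 0. Gcsam stood at 217.9 CPM in A20 and was listed at 0 in MPC11, and the signal kinase gene Prkcb went from 2066 to 1.17 CPM. The cyclin Ccnd2 went the other way, from 0.359 to 1005 CPM.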

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

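Tests on the first libraries, on macrophage genes and on Y-linked genes were chosen only after the result was seen, while the counts of splits and of the interaction were planned. The difference of the plasmablast effect between LPS and CD40L cultures was marked for attention because it gave 3250 genes whose change from blast to plasmablast differed between 2 culture systems. The cultures differed in stimulus, hours and cytokines, and the LPS arm rested on 1 blast library. With immunoglobulin genes removed the count was 3270, with the DESeq2 Wald test 3401, with library totals 4910, and with only the groups compared in the fit 6721. Stimulus, hour of harvest and the lone blast library were not separated as causes.

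The first FoB and first B1 libraries differed from their partners along the same genes, with a correlation of 0.686 across genes. After a trend on transcript length was taken out the correlation was 0.712, which argues against length bias. Counting noise is independent between libraries at any level, so it cannot give a shared pattern of this size. The correlation was also 0.686 over 1800 genes of at least 100 CPM. Since independent noise could not produce that value in any case, this check adds no evidence on counting noise. Over 8133 protein-coding genes without ribosomal protein genes the correlation was 0.548. Genes with close relatives, such as Mfap1a and Mfap1b, did not count as copies. The value therefore cannot decide whether reads shared with near-identical copies are the whole cause. Among the 216 genes that moved at least 2-fold the same way in both pairs, 52.3% were of copy classes, against 6% of all genes, so such reads may explain the strongest shifts. A shared day of handling or of sequencing could also account for the pattern and stays open, since no label records it.

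Macrophage genes were higher in the first B1 library than in the second, with a list median difference of 3.85 log2, against 1.61 between the FoB libraries. Of 20 members, 16 were at least 2-fold higher in the first B1 library but 18 in the first FoB library, so that count does not set the peritoneal library apart. Macrophage RNA passing the gate on B220, low Mac1 and absent CD23 may still add to the larger median, and Lyz2 was at 1492 CPM in that library and 101.7 CPM in its partner. A lower share of B1 RNA would raise markers of other cells alike, yet the macrophage median exceeded the T cell median by 2.85 log2, which argues against it. Transcription of these genes by B1 cells themselves and the shift shared by both first libraries stay open.

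Y-linked genes and Xist differed between libraries. Of 29 primary libraries 10 had Y-linked genes under 1 CPM, 9 had Xist under 1 CPM, 10 had both above it and 0 had both under it, consistent with mice of different sex and with pools of both. Regulation with differentiation is an unlikely source, since the sum of Y-linked CPM ranged 157.3-fold among the 3 splenic plasma cell libraries. Y-linked genes were at 0.168 CPM at division 1 and 82.8 CPM at division 7, so differences along the division series, of these and of other genes, may come from the animals. Sex followed the arms in part when ex vivo secreting cells were set against B cells and tissue against culture, and whether it moved other genes there was not tested.

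In a 2-arm fit of ex vivo secreting cells against B cells, 1 of 100 splits (the real one, with 7379 genes) gave as many calls. The highest of the others gave 170. Every other split mixes unlike populations within an arm, which adds spread and lowers the calls whatever the cause. The test therefore cannot decide on chance. For tissue plasma cells against cultured plasmablasts, 1 of 100 splits (the real one, with 4446 genes) gave as many, and the highest of the others gave 2852. That split kept 4 of the cultured libraries together, so it points to the same structure of the samples. For the same reason as above, these splits cannot decide on chance.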

How the results depend on the processing

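Across all settings, 18732 results of named genes were compared with the values reported, of which 17690 kept call and direction, 1003 lost their call and 39 changed direction. The planned count source alternative was not run, since the per-sample files hold log2 FPKM values, and limma on those values was added in its place after the data were seen. Also added after seeing the data were the replicate block in a fit of the 2 groups, its crossed form, and the runs that left out or thinned libraries or left out markers of other cells. Per setting, lost calls numbered 14 of 1089 with DESeq2 size factors, 8 of 1089 without a filter, 2 of 1061 with a filter of at least 1 CPM in 3 libraries, 13 of 1075 without immunoglobulin genes, 51 of 1089 by the DESeq2 Wald test, 69 of 1089 by limma-voom, 60 of 1073 by limma on FPKM, 146 of 1070 with only the groups compared in the fit and 40 of 232 in 2-arm fits. The 300 list results take in all lists in all contrasts, called or not, whereas the gene results above were all called. Only the lists called at the preset correlation could lose a call, so 300 is not the base for losses. With an estimated correlation 74 lost their call. With fry 16 lost and 59 gained a call, and with the replicate block in camera 2 lost and 4 gained one. The cause was not tested for any change given here. Depth limits calls for genes near the filter, and the deepest libraries were those of germinal center cells.

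Library totals gave 86 lost calls and 22 reversals among 1089. Counts of called genes became 11778 for LPS plasmablasts and 10719 for Syndecan1-negative plasmablasts against blasts, 5268 between the LPS plasmablasts, 5357 for splenic plasma cells against plasmablasts, 4910 for the interaction and 6109 for the signature. In ex vivo secreting cells against B cells Itgb3 went to -0.48, Zbtb20 to -0.05, Atf4 to -0.1, Pou2af1 to -0.68 and Tcf4 to -0.8. In LPS plasmablasts Cdk1 went to -0.17, Cdc45 to -0.23, Bst2 to -0.48, Atf6 to -0.32 and Tcf4 to -0.61. In Syndecan1-negative plasmablasts Mcm6 went to -0.02, Tcf4 to -0.3 and Atf6 to -0.19. Between the LPS plasmablasts Srprb and Ganab went to -0.08, Mogs to -0.07 and Dpagt1 to -0.09. In CD40L/IL4/IL5 plasmablasts Tcf3 went to -0.26. In tissue plasma cells against culture Creb3l2 went to -0.08, Tcf4 to -0.16, and Xbp1 and Ikzf3 to -0.36.

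Bone marrow against splenic plasma cells gave 60 genes without immunoglobulin genes, 210 by the DESeq2 Wald test, 183 by limma on the deposited FPKM values and 4 with only the groups compared in the fit. With only the groups compared, the LPS plasmablasts differed in 2397 genes, marginal zone from follicular cells in 2845, B1 from follicular cells in 959, splenic plasma cells from plasmablasts in 637, and the interaction gave 6721. In 2-arm fits the ex vivo comparison gave 7379 and tissue against culture 4446, with Gcsam at -1.04 in the latter. Constant regions alone gave an immunoglobulin difference of 45.45 points. By limma on FPKM values Cd74 in marginal zone cells was at 0 and Ikzf1 in tissue plasma cells against culture at 0.02. With division libraries as the reference arm of CD40L/IL4/IL5 plasmablasts, Vcam1 went to 0.7, Spic to 0, Gzma to -3.29, Bhlhe41 to -0.09 and Myc to -0.41.

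Replicate numbers in the labels could pair libraries across groups. Added to the fit of all groups, the replicate block gave 11239 genes in the ex vivo comparison and lost 32 of 1089 calls. Change between first and second libraries correlated at 0.686 for FoB and B1, 0.446 for the LPS plasmablasts, 0.196 for FoB and GCB, 0.043 for CD40L blasts and plasmablasts and -0.151 for FoB and MZB, over 8949 genes of at least 10 CPM. In a fit of the 2 groups the block gave 5165 genes between the LPS plasmablasts, 2087 for marginal zone and 3099 for B1 against follicular cells, and crossed for marginal zone cells 2266.

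Without 1 library at a time, counts ran from 11081 to 11693 for ex vivo secreting against B cells, 6448 to 6495 for LPS plasmablasts, 5540 to 5660 for Syndecan1-negative plasmablasts, 201 to 610 between them, 7214 to 7389 for CD40L/IL4/IL5 plasmablasts, 4060 to 6322 for marginal zone, 4253 to 6198 for B1 and 7072 to 8573 for germinal center cells. They ran from 1378 to 1908 for splenic plasma cells, 94 to 165 for bone marrow, 8971 to 9747 for tissue against culture, 2375 to 2514 for the interaction and 2156 to 2299 for the signature. Without the first SplPC library bone marrow gave 165, and without the first MZB library marginal zone cells gave 4060. Between the LPS plasmablasts, 610 and 201 were called without the first and second Syndecan1-negative library, 311 and 373 without the first and second Syndecan1-positive one. Without the first FoB library, alone or with the first B1 library, Hspa1a in marginal zone vs follicular B cells went to 1.51 and Vcam1 in germinal center vs follicular B cells to 0.11, and without the second FoB library they went to -6.85 and -2.3. Without the CD40L/IL4 plasmablast library, tissue against culture gave the high end of the ranges of Fcer2a (-2.5 to 0.12), Bach2 (-0.51 to 0.4), Pou2f2 (-0.44 to 0.06), Foxo1 (-0.41 to 0.23) and Ikzf1 (-0.24 to 0.03).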

Other observations

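Isotype shares were computed only after the data were seen and were not tested. Among heavy-chain constant counts, Ighe took 47.26% (95% Wilson interval 47.2 to 47.33) and Ighg1 32.41% (32.35 to 32.47) in the CD40L/IL4 plasmablast library, while in the CD40L/IL4/IL5 plasmablast libraries Ighe took 0.455% (0.4511 to 0.459) and 0.6081% (0.6033 to 0.6129). Along the division series Ighe took 5.077% (4.956 to 5.201) at division 1, 2.643% (2.578 to 2.71) at division 3, 4.1% (4.018 to 4.184) at division 5 and 19.54% (19.41 to 19.67) at division 7. Between divisions 1 and 7 Ighg1 went from 12.51% (12.33 to 12.69) to 48.73% (48.57 to 48.9). Cells of these divisions had IL5 and 96 hours of culture. The CD40L/IL4 plasmablasts had 96 hours without IL5, and the CD40L/IL4/IL5 plasmablasts 120 hours. Stimulus, hour and sort gate were thus not separated in these shares. In LPS plasmablasts Ighm took 99.22% (99.22 to 99.23) and 99.08% (99.08 to 99.09). Bone marrow plasma cells had Igha at 40.35% (40.33 to 40.38), against 8.257% (8.244 to 8.27), 18.87% (18.85 to 18.89) and 21.3% (21.28 to 21.32) in the splenic ones and 4.938% (4.926 to 4.95) in splenic plasmablasts. Follicular B cells held Ighd at 21.56% (21.36 to 21.77) and 25.2% (25.02 to 25.38), B1 cells at 0.9786% (0.936 to 1.023) and 2.161% (2.114 to 2.209). In MPC11 Ighg2b took 98.58% (98.54 to 98.62).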
